A study of Homo sapiens with 12 samples.

How the data were processed

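Small RNA libraries of spontaneously formed NETs were sequenced on a HiSeq2500, after RNA isolation with the ExoMir kit, in 12 libraries: 6 of control and 5 of SLE normal-density neutrophils and 1 of SLE low-density granulocytes. Per the labels, reads were called with bcl2fastq 1.8.4 and coordinates are those of hg19; the aligner and the counting tool are not stated. The deposited values are RPKM made by the authors, 1 column per library, for 6446 intervals of 16 to 1140 nt (median 43 nt) annotated with HOMER, whose gene name is that of the nearest promoter. Interval lengths were taken as end minus start.

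RPKM times interval length was a whole multiple of 1 step per library in 97.8% to 99.2% of the values above 0 (tolerance 0.01 read, or a relative 1e-05). The step gave each library's total of reads, from 8721 to 1777203, a ratio of 203.8 between the deepest and the shallowest. Intervals listed in the table held 41.2% to 66.8% of these totals. In 3 libraries (SLE replicates 2 and 5 and the LDG library) the total was below 20000. Shares of reads in the LDG library carry 95% Wilson intervals, and the floor for a count of 0 is 3 reads.

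Intervals were put in 12 classes from their biotype, repeat and gene annotation: tRNA, rRNA, Y RNA, snRNA, snoRNA, miRNA, mitochondrial, other small RNA, protein-coding transcript, other transcript, unannotated, and the chromosome 21 interval alone, a class made after its values were seen. Shares of the summed RPKM and numbers of intervals above 0 were averaged per code and compared between 4 SLE and 4 control codes with two-sided exact permutation tests (70 assignments), with Benjamini-Hochberg adjustment over the 12 classes. Matching codes were taken from the titles. Libraries of a code correlated at r = 0.92, 0.95 and 0.87 over 168 intervals, against 0.58 to 0.92 (median 0.74) for other pairs within a group. As deviations from the group mean, r was 0.41 and 0.69 for the control codes and 0.09 for the SLE code. SLE replicate 4 was closest to control replicate 1 (r = 0.89), so the values do not bear out the pairing of the SLE code. These are correlations across intervals, which are not independent replicates.

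SLE was compared with control with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1) over the 1106 intervals with at least 1 RPKM in 5 of the 11 libraries of normal density. The model had condition and the colour word, the code as a random block (duplicateCorrelation, consensus correlation 0.74), and moderated statistics with a trend and robust estimation. Adjusted p-values are Benjamini-Hochberg, with a threshold of 0.05. YELLOW was compared with BLUE over the 6 libraries of the 3 codes with both words, with the code as a fixed block. The LDG library was compared with SLE in a model of the 3 groups without colour (1113 intervals), which takes its spread from the other groups, beside a count of intervals 4-fold or more outside the range of the SLE libraries. Lists of RNAs were tested with cameraPR on the limma statistics with a correlation of 0.01, for the 13 lists with 3 or more tested intervals. Camera with an estimated correlation and fry with the code as block were run beside it; fry asks whether a list's intervals move one way on balance and does not compare it with other intervals. The fry adjusted p was 0.0409 for all miRNA, 0.0409 for myeloid miRNA, 0.0409 for inflammation miRNA, 0.0216 for vault RNA and 0.169 for rRNA, each in the direction lower in SLE. Camera with an estimated correlation gave an adjusted p of 0.639 for each of these lists. The median log2 fold change of all tested intervals was -2.63, so fry can pass a list that only shares this shift.

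The comparisons, their tests, the lists, the alternatives first listed and the rule for named intervals were fixed before the data were examined. The rule takes intervals past the threshold by fold change, then the 8 with the smallest p per direction, up to 4 per list by mean level, and the 10 highest in control. To keep the text short, this was narrowed after the values were seen, in the rule's own order, to the 5 smallest p per direction for SLE against control, 3 per direction for YELLOW against BLUE, the 4 past the threshold for LDG and the first 2 per list, 49 intervals in all, 2 of them in 2 comparisons. Let-7i, HY4 on chromosome 3, MIR146B and others so named appear where their values change with the processing, and the fuller set was not tried under the alternatives.

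Alternatives were pseudocounts of 0.1 and 10, no filter, a filter at 10 RPKM, quantile normalization, median centring, limma without trend and robust estimation, no block, averaged codes, no colour term, each colour alone, and each library left out. Added after the data were seen were a pseudocount of 1 read of the shallowest library, limma-voom on the recovered reads with the recovered totals as library sizes, leaving out SLE replicates 2 and 5, leaving out control replicates 2, 3 and 4, class shares within the YELLOW libraries, numbers of intervals drawn down to 5295 reads, and the interaction of condition and colour. The last had 0 of 1106 intervals past the threshold in limma (smallest adjusted p 0.85, with 52 at an unadjusted p under 0.05). In some alternative fits limma offset near-zero variances from 0. Count models on whole reads were planned only for deposited counts and were not run.

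The main model was tested on simulated data of the same layout and totals, with dispersions capped at the median of the observed ones and libraries drawn without a shared code, which favours recovery. Of 88 intervals simulated with an absolute log2 fold change of 3, 9.1% passed, and of 85 with 5, 37.6% passed, with 0 unchanged intervals called. With a dispersion 0.1 times as large, 22.9% of 96 and 64.1% of 92 passed, with 3 unchanged intervals called. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.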

Results

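Small RNA was sequenced from neutrophil extracellular traps (NETs), the webs of chromatin and granule protein that neutrophils release, which here formed without an added stimulus. The NETs came from normal-density neutrophils of healthy controls in 6 libraries and of patients with systemic lupus erythematosus (SLE), an autoimmune disease, in 5 libraries. A further library came from low-density granulocytes (LDG), neutrophil-like cells that sediment with mononuclear cells, of SLE. The study's title sets RNA carried out of cells by NETs beside inflammation in endothelial cells, so the question here was which small RNAs NETs hold and whether they differ between SLE and control. Control replicates 3 and 4 share a sample code, as do control replicates 5 and 6 and SLE replicates 3 and 4, which leaves 4 codes in each group. The titles also carry the word BLUE or YELLOW, whose meaning is not stated.

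The deposited table gave RPKM, a read density scaled to interval length and to the library's total, for 6446 intervals, of which 3142 were listed at 0 in all 12 libraries. Whole-read steps in the values put the control totals at 603357, 1442546, 1777203, 1572620, 1588946 and 500063 reads for replicates 1 to 6. The SLE totals were 357543, 13127, 986548, 1651337 and 8721 reads for replicates 1 to 5, and the LDG library had 13227. A class with no read could still hold up to 0.0383% and 0.0567% of the listed reads in SLE replicates 2 and 5 and 0.0396% in the LDG library (3 reads), against 0.00204% or less in the other 9 libraries. Intervals and floors of this kind cover counting error only, since reads copied by PCR are not independent molecules. For SLE against control, the permutation p-values measure the spread between codes. The limma p-values measure the spread between libraries, with the code as a block. Whether each code is 1 person was not established, so neither is read as the spread between people.

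In control NETs the listed intervals held 47.1% to 59.7% of each library's reads, mostly fragments of ribosomal RNA (rRNA) and transfer RNA (tRNA). Y RNA, small RNAs bound by the Ro protein, a lupus autoantigen, came after unannotated intervals. Of the reads in listed intervals, rRNA took 42.6% ± 9.05 (SD, n = 6 control libraries), tRNA 20.2% ± 9.56 and Y RNA 6.64% ± 3.09. An unannotated interval on chromosome 21 (hg19, 9826870 to 9827582, 712 nt), set apart after its values were seen, took 12.6% ± 4.16, and the other unannotated intervals took 14.1% ± 2.9. The chromosome 21 interval had no gene or repeat name, so its RNA class is unknown. The rRNA shares given here leave it out and would be too low if it held rRNA. Small nuclear RNA (snRNA) made up 2.16% ± 0.687, small nucleolar RNA (snoRNA) 0.741% ± 0.182 and microRNA (miRNA) 0.131% ± 0.0651. In SLE the same classes took 51.3% ± 11.9 (rRNA, SD, n = 5 libraries), 7.26% ± 5.07 (tRNA), 2.49% ± 2.57 (Y RNA), 26.2% ± 13.2 (the chromosome 21 interval) and 0.0666% ± 0.0299 (miRNA). The Y RNA mean was raised by SLE replicate 1, at 6.97% against 0.499% to 1.92% in the other SLE libraries.

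The highest control interval was a tRNA-Glu-GAG copy on chromosome 1 (249168420 to 249168479), at 549193 ± 429328 RPKM (SD, n = 6) against 134115 ± 129887 in SLE (n = 5). Among the 10 highest intervals 3 were tRNA-Gly-GGY copies, on chromosome 16 (from 70823402 and from 70822596) and chromosome 17 (from 8029049). They had control means of 279986, 277784 and 244759 RPKM and SLE means of 86166, 108794 and 83504 RPKM. The Y RNA HY4 copy on chromosome 7 (148660397 to 148660450) stood at 166927 ± 77523 RPKM in control and 72608 ± 71234 in SLE. A further 2 were small-subunit rRNA, the part of the ribosome that reads messenger RNA. The copy in an intron of PDE3A on chromosome 12 (20704362 to 20704511) had 330045 ± 226153 RPKM in control and 166379 ± 145939 in SLE. The copy on chromosome 16 (33963696 to 33963756) had 286149 ± 150264 and 577846 ± 392901. The remaining 3 were unannotated: near the promoter of GFM2 on chromosome 5 (from 74063437), in an intron of SLC4A7 on chromosome 3 (from 27525468) and on chromosome X (from 108297713). They had control means of 355462, 232727 and 214971 RPKM. Copies of tRNA, Y RNA and rRNA genes are near identical, so the copy that a read was placed on is uncertain.

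**Figure D1:**
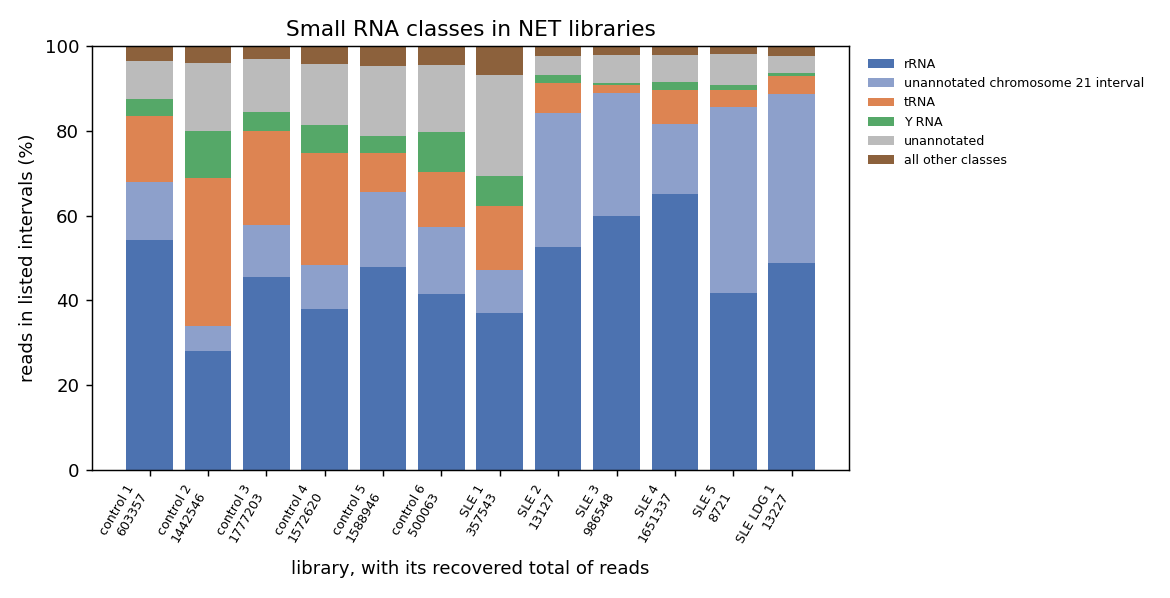
Stacked bars show the percent of reads in listed intervals (y axis) that each RNA class took in each of the 12 libraries (x axis, with the library's recovered total of reads). The chromosome 21 interval took 39.8% of the reads of the LDG library and a mean of 12.6% in the 6 control libraries.

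Between SLE and control, the tRNA share of the summed RPKM was lower in all 4 SLE codes than in any control code, at 11.8% ± 4.21 against 26.9% ± 8.43 (SD of per-code means, n = 4 codes each), a difference of -15.0 points. Without control replicate 6, 2 of 4 SLE codes lay below the lowest control code (exact permutation p = 0.0857), and as shares of reads 3 of 4 did (p = 0.0571). Without control replicates 2, 3 and 4 the tRNA difference was -8.55 points (exact permutation p = 0.133). Y RNA took 3.89% ± 1.99 in SLE against 8.21% ± 2.46 in control, with 3 of 4 SLE codes below the lowest control code. The rRNA share was 50.1% ± 19.6 in SLE against 34.9% ± 13. The chromosome 21 interval took 4.76% ± 3.37 against 1.33% ± 0.607, and both had 3 of 4 SLE codes above the highest control code. As shares of reads the rRNA difference, which leaves out the chromosome 21 interval, was 6.23 points (exact permutation p = 0.486), with 1 of 4 SLE codes above the highest control code. The rRNA difference of 15.1 points in the summed RPKM was 9.66 without control replicate 2, 24.7 without SLE replicate 1, 8.37 without SLE replicates 2 and 5 and 5.22 without control replicates 2, 3 and 4. The chromosome 21 difference of 3.44 points was 2.05 without SLE replicate 5, 1.04 without SLE replicates 2 and 5, and 4.76 without SLE replicate 1 (exact permutation p = 0.0286, adjusted p = 0.171). The miRNA share was 0.119% ± 0.0458 in SLE and 0.149% ± 0.0617 in control. The shares of a library add up to a fixed whole, so a lower tRNA share and a higher rRNA share are not separate results. No class passed the adjustment over the 12 classes. The two-sided exact permutation p was 0.0286 for tRNA, the smallest that 70 assignments can give, 0.0571 for Y RNA, 0.229 for rRNA and 0.114 for the chromosome 21 interval, and the smallest adjusted p was 0.343. Within the BLUE libraries (3 against 3, smallest possible exact p 0.1) the SLE minus control difference was -10.9 points for tRNA (p = 0.3), -1.99 for Y RNA (p = 0.3), 4.33 for rRNA (p = 0.8) and 2.28 for the chromosome 21 interval (p = 0.4). Within the YELLOW libraries (3 against 2, smallest possible exact p also 0.1) it was -18.9 for tRNA (p = 0.2), -7.61 for Y RNA (p = 0.2), 34.4 for rRNA (p = 0.1) and 4.39 for the chromosome 21 interval (p = 0.1).

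**Figure D2:**
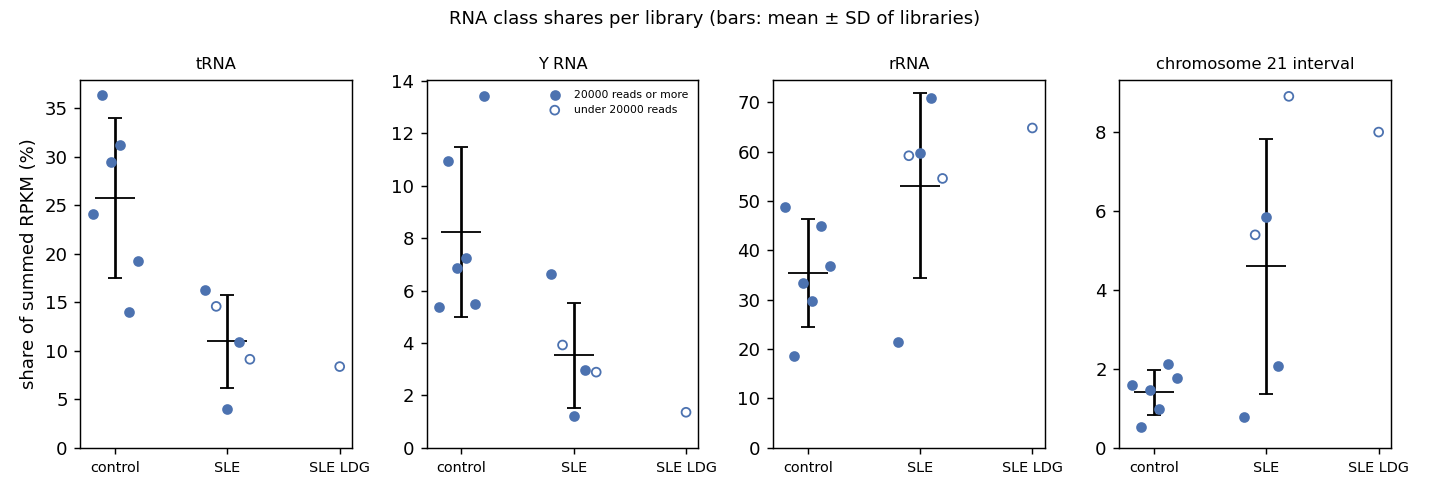
Points give the share of the summed RPKM (y axis, percent) of tRNA, Y RNA, rRNA and the chromosome 21 interval in each library of each group (x axis), and bars give the mean ± SD of libraries. Open circles are libraries under 20000 reads. The tRNA share averaged 25.7% in the 6 control and 11% in the 5 SLE libraries, a difference that did not pass the adjustment over 12 classes.

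Fewer intervals had a read in SLE, 693.5 ± 568 against 1406 ± 161 in control (SD, n = 4 codes each), with an exact permutation p of 0.0571. Read totals differ between the groups, and drawn down to the 5295 listed reads of the shallowest library the numbers were 222 ± 31.3 and 265 ± 19.7, with an exact permutation p of 0.0857. The difference in intervals with a read, -712.5, was -251.5 without SLE replicates 2 and 5 (exact permutation p = 0.267), -472.8 in the YELLOW libraries (p = 0.7), and -774.5 without SLE replicate 4 (p = 0.0286, the smallest possible).

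Interval by interval, those with the smallest p at higher means in SLE were an L1M4 repeat, a tRNA-Gln-CAG copy, 2 rRNA fragments and SNORD49A. In limma the unadjusted p was 0.00876 for the repeat, 0.0553 for the tRNA and 0.0653 for the first rRNA fragment. At lower means they were tRNA, transcript and unannotated intervals. Small-subunit rRNA on chromosome 16 (33963513 to 33963594) had 137807 ± 63981 RPKM in SLE (SD, n = 5) and 45013 ± 18314 in control (n = 6). That on chromosome 2 (133012688 to 133012797) had 115509 ± 57831 and 48486 ± 72392. Its control mean rests on control replicate 1, at 194128 RPKM against 6824 to 38986 in the other control libraries. An unannotated L1M4 repeat on chromosome 7 (48672360 to 48672403) had 170961 ± 88412 and 39916 ± 29191. The tRNA-Gln-CAG copy on chromosome 4 (from 134189620) had 5262 ± 5776 (2805 without the shallow SLE replicate 5) and 533 ± 645. SNORD49A, a snoRNA that guides rRNA methylation, had 888 ± 1327 and 75.2 ± 55.2. Its SLE mean rests on the shallow SLE replicates 2 and 5, at 1044 and 3142 RPKM, against 66.4 to 111 in the other 3. At lower means in SLE stood a tRNA on chromosome 17 (8022453 to 8022505), with 354 ± 506 RPKM against 18841 ± 23963, and tRNA-Thr-ACA on chromosome 1 (from 222638320), with 25.7 ± 41.4 against 583 ± 309. The 5' UTR of PTMS on chromosome 12 (6875676 to 6875697) was listed at 0 in all 5 SLE libraries against 172 ± 132 RPKM in control. Unannotated intervals at SLC22A15 (chromosome 1, from 116519475) and NEUROD6 (chromosome 7, from 31376253) had 100 ± 161 against 2417 ± 2768 and 40.4 ± 65.8 against 636 ± 351. In SLE replicates 2 and 5 (13127 and 8721 reads) 1 read at PTMS, tRNA-Thr-ACA, SLC22A15 or NEUROD6 exceeds the control mean. Each of these intervals was at 0 in both libraries, and those zeros cannot show a lower level.

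None of the 1106 tested intervals passed an adjusted p of 0.05 in limma with the code as a block and colour as a term, where the smallest adjusted p was 0.249. At an unadjusted p under 0.05 stood 213 intervals, 1 higher and 212 lower in SLE. Of the 35 splits of the 8 codes, not planned for this count, 2 gave as many, the real one included, and the other gave 274. Limma-voom on the recovered reads also passed 0, with 53 at an unadjusted p under 0.05 (30 higher and 23 lower). The median log2 fold change over all tested intervals was -2.63, so fold changes count only relative to it. It moved to 0.22 with quantile normalization, 1.0 with median centring, 0.72 with voom and -0.68 without SLE replicates 2 and 5. It also depends on the pseudocount, at -4.17 with 0.1, -1.35 with 10 and -0.03 with 1 read of the shallowest library, and was -0.79 without a filter on low values. Leaving out SLE replicate 4 gave 31 intervals lower in SLE (PTMS, tRNA-Thr-ACA and the chromosome 17 tRNA at adjusted p = 0.0461). The YELLOW libraries alone (3 against 2) gave 29, with 2 higher and 27 lower in SLE, against 0 in the BLUE libraries. Of the YELLOW SLE libraries, replicates 4 and 5, the latter had 8721 reads and 210 intervals above 0. The fit without SLE replicate 4 kept the shallow SLE replicates 2 and 5. Neither count can thus be told apart from a difference in depth, although the BLUE libraries also hold the shallow SLE replicate 2.

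Of the groups of RNAs fixed before the data were examined, 13 had 3 or more tested intervals, and 2 miRNA lists ranked below and the rRNA list above the other intervals in SLE in a competitive test on the limma statistics with a preset correlation. With an estimated correlation none of the 3 held (adjusted p = 0.639 for each list). All 44 tested miRNA intervals had a fitted fold change below 0 (median log2 -3.52), as did the 12 of the neutrophil and myeloid miRNA list, all of them also in the miRNA list (median -4.84). MIR223, the miRNA most typical of granulocytes, had 812 ± 1236 RPKM in SLE (SD, n = 5) and 2171 ± 1145 in control (n = 6), and MIR21, which is raised in inflammation, 119 ± 129 and 1107 ± 752. MIR24-1 ran the other way in its means, with 758 ± 667 and 436 ± 319, and MIR26B had 1069 ± 1638 (348 without the shallow SLE replicate 5) and 1176 ± 597. With the preset correlation both miRNA lists ranked below the other intervals at an adjusted p of 0.0222. The rRNA list ranked above them at an adjusted p of 0.00301, although 93 of its 118 intervals had a fold change below 0 (median -2.0), so its direction is relative to the other intervals and differs in sign from its median. Quantile normalization also passed 3 lists, with myeloid miRNA kept (0.0442), rRNA (0.515) and all miRNA (0.414) lost, and mitochondrial RNA ranked above (0.00591) and tRNA below (0.0442) the other intervals. The preset correlation passed 0 lists without control replicates 2, 3 and 4. As ratios of group means, with members at 0 set at 3 reads over the group, the median log2 ratio was -1.95 for miRNA (4 of 44 at 0 in SLE), -2.55 for the myeloid list (1 of 12), -0.47 for rRNA and -0.98 for all tested intervals. By these means 41 of 44 miRNA, 11 of 12 myeloid miRNA and 72 of 118 rRNA intervals were lower in SLE, against 802 of all 1106. No member of any list passed over all intervals. Adjusted over the list alone 2 of 3 vault RNA and 2 of 4 7SK and 7SL RNA intervals passed and none in the other 11 lists.

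The remaining lists did not pass. Counts by the sign of the fitted fold change depend on the pseudocount and on zeros in the shallow SLE libraries. Of 236 tested tRNA intervals 220 had a fitted fold change below 0 (median -3.00, adjusted p = 0.184), as had 21 of 22 Y RNA (-1.96, 0.608), 39 of 43 snRNA (-2.30, 0.934) and 104 of 119 snoRNA intervals (-2.89, 0.913). By the ratio of means 188 tRNA, 15 Y RNA, 36 snRNA and 86 snoRNA intervals were lower. The spliceosomal U1 on chromosome 1 (from 148241462) had 3647 ± 1869 RPKM in SLE and 11520 ± 6522 in control, and the snoRNA SNORD104 12284 ± 11637 (7507 without SLE replicate 1) and 11134 ± 3374. With median centring the log2 fold changes of tRNA-Glu-GAG, HY4 on chromosome 7 and U1 turned from -1.92, -1.24 and -1.41 to 1.69, 2.36 and 2.20. Only 255 and 210 intervals were above 0 in SLE replicates 2 and 5, so their median over the 1106 tested intervals is 0. Centring then raises every value of these libraries relative to the deeper ones, and these turns cannot be told apart from depth. Vault RNA, the RNA of large cytoplasmic ribonucleoprotein particles, was lower in 3 of 3 by both counts (-5.29, 0.108), with VTRNA1-1 at 522 ± 832 RPKM in SLE and 1907 ± 1849 in control. The list of 7SK and 7SL RNA held 4 tested intervals, all of 7SL, the RNA of the signal recognition particle, and 4 of 4 were lower by both (-3.22, 0.913). The let-7 family had a fitted fold change below 0 in 6 of 6 (-3.46, 0.581) but lower means in 5, since MIRLET7I averaged 309 RPKM in SLE (71.4 without the shallow SLE replicate 2) and 102 in control. Inflammation miRNA was lower in 4 of 4 by both (-3.56, 0.266). For mitochondrial RNA 23 of 25 were lower by the fit (-1.86, 0.329) and 19 by means, and for messenger RNAs of mature neutrophils 2 of 3 by the fit (-1.88, 0.261) and 0 by means. Both lists ranked above the other intervals in the test, against the sign of their fitted medians. Among the latter, the 5' ends of B2M and SRGN, a proteoglycan of neutrophil granules, had higher means in SLE (303 ± 499 and 146 ± 229 RPKM) than in control (111 ± 66.0 and 70.1 ± 62.4). Each rests on 1 library, and both turn to lower, with 85.5 for B2M without SLE replicate 2 and 45.7 for SRGN without SLE replicate 3. Lists for granule proteins, lymphocytes, and eosinophils and basophils matched 0 intervals. The lists for erythrocytes (1 interval matched), platelets (2), monocytes (3), interferon-stimulated genes (7), inflammatory cytokines (2), histones (22) and ribosomal proteins (29) had fewer than 3 tested intervals. RPLP1, the ribosomal protein interval tested, had 9.55 ± 11.2 RPKM in SLE and 13.5 ± 11 in control.

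The BLUE and YELLOW libraries of the same code had their smallest p in rRNA fragments. An rRNA interval on chromosome 16 (33965562 to 33965588) had 275630, 182593 and 100385 RPKM in the YELLOW and 45036, 60127 and 12047 in the BLUE libraries of the 3 codes that hold both words. Small-subunit rRNA on chromosome 2 (from 133011913) was also higher in YELLOW in 3 of 3 codes. An unannotated interval on chromosome 8 (from 85861773) had 4324, 10699 and 272 RPKM in YELLOW and 450, 2045 and 0 in BLUE. The PDE3A copy of small-subunit rRNA was lower in YELLOW in 3 of 3 codes, with 212227, 151350 and 110112 against 777767, 314269 and 423087 RPKM. Unannotated intervals at SLC35F3 (chromosome 1, from 234040763) and USP34 (chromosome 2, from 61698220) were lower in YELLOW in 3 of 3. None of 1106 intervals passed in limma with the code as a block (smallest adjusted p 0.77), with 57 at an unadjusted p under 0.05 (49 higher and 8 lower in YELLOW). Other splits of the 6 libraries, not planned for this count, gave up to 156 at an unadjusted p under 0.05. With voom 0 passed (91 at an unadjusted p under 0.05). Leaving out control replicate 3 or control replicate 4 gave 1 interval each, the fit without a filter on low values 16, and the colour term over 11 libraries 3, the chromosome 16 rRNA interval among them (adjusted p = 0.0413).

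The LDG library held rRNA at 48.9% of listed reads (95% Wilson interval 47.8 to 50.0) and the chromosome 21 interval at 39.8% (38.7 to 40.9), with tRNA at 4.40% (3.96 to 4.89), Y RNA at 0.661% (0.502 to 0.87) and miRNA at 0.0661% (0.0282 to 0.155). Its tRNA, rRNA and chromosome 21 shares lay inside the range of the 5 SLE libraries of normal density, which ran from 1.81% to 15.2%, from 37.0% to 65.1% and from 10.2% to 43.8%. The Y RNA share was also inside theirs, at 0.499% to 6.97%. Its unannotated share of reads, 3.85% (3.44 to 4.30), lay below the lowest SLE library, at 4.56% (4.12 to 5.05). Its miRNA share of the summed RPKM, 0.297% from 5 reads, lay above the highest, at 0.186%. Neither held in the other measure. The unannotated share of the summed RPKM, 11.3%, lay inside the SLE range of 10.4% to 48.0%. The miRNA share of reads lay inside that of 0.0356% to 0.107%. Let-7b (MIRLET7B) stood at 6574 RPKM from 2 reads, against 218 ± 250 in SLE (SD, n = 5) and 607 ± 565 in control (n = 6).

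Against the SLE libraries of normal density, 4 of 1113 intervals were lower in the LDG library in limma, where the lone library is assumed to vary as the others do. They were a 7SL RNA fragment on chromosome 13 (45576360 to 45576385), an unannotated LTR12C repeat on chromosome 5 (157120867 to 157120885), a tRNA on chromosome 14 (73429716 to 73429763) and a tRNA-Val-GTA copy on chromosome 11 (59318140 to 59318189). Their limma adjusted p were 0.00446, 0.00623, 0.0359 and 0.0438. Their SLE means were 10107 ± 8535, 7784 ± 7744, 3252 ± 2879 and 2236 ± 2338 RPKM (SD, n = 5). Without SLE replicate 2 the means of the repeat and of tRNA-Val-GTA were 4440 and 1240, and without SLE replicate 4 that of the chromosome 14 tRNA was 1991. Each was at 0 reads in the LDG library where 3.3, 1.9, 2 and 1.4 reads were expected from the SLE mean, where Poisson counting gives 0 reads with an exact probability of 0.0354, 0.157, 0.132 and 0.235. For the last 3 a lower level was not detectable at this depth, and the first probability is not adjusted for the 4 intervals. By range, 45 intervals lay 4-fold or more above the highest and 26 below the lowest SLE library, against 1 and 0 with a pseudocount of 1 read of the shallowest library. Each SLE library set against the other 4 in the same way gave 22 to 148 above and 0 to 85 below. Leaving out SLE replicates 2 and 5 sets the LDG library, at 13227 reads, against SLE libraries of 357543 reads or more. The median log2 fold change was then -3.66, against -1.93 in the main fit. The count given below for that setting thus cannot be told apart from a difference in depth. The same holds for median centring. The LDG library had 262 intervals above 0, so its median over the tested intervals is 0 and centring raises all its values. With voom 0 passed (0 at an unadjusted p under 0.05), with median centring 61 passed as higher and 0 as lower, and without SLE replicates 2 and 5 the count was 279 (9 higher and 270 lower). Leaving out libraries in turn gave 9, 24 and 40 without SLE replicates 1, 2 and 5 and 2 without each of control replicates 1, 3, 4, 5 and 6. Quantile normalization and limma without trend and robust estimation gave 0 (80 and 105 at an unadjusted p under 0.05).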

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

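Of the tests below, those without SLE replicates 2 and 5, those without control replicates 2, 3 and 4, the pseudocount of 1 read, voom, the regroupings by median, quantile normalization as a test of depth, the zeros of intervals expected as often as the LDG calls, the thinned draws as a test of the rRNA rank, and the estimated correlation as an account of the list ranks were chosen only after the result was seen; the other regroupings, the thinning of reads as a test of the median and the test of LDG zeros at 3 or more expected reads were fixed earlier.

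Most tested intervals had a fitted fold change below 0 in SLE (median log2 -2.63), while 0 passed the threshold in limma, with 213 at an unadjusted p under 0.05 and 0 by voom (53 at an unadjusted p under 0.05). The median was 0.72 with voom and 0.22 with quantile normalization, so even its sign depends on the processing. That 35 of the 35 splits of the 8 codes gave as many past the threshold (highest other 1) follows from the real count of 0 and says nothing, but 2 of the 35 gave a median as far from 0 (2.63 in the real split, 2.68 in the highest other), so chance is not excluded. Control replicates 2, 3 and 4 stand apart on the first principal component (18.5, 11.5 and 14.3 against 2.6 or less, 45.8% of the variance). They are argued against as the whole source, since without them the median was -2.78. That fit kept the shallow SLE replicates 2 and 5, and no fit left out both sets of libraries. Whether these controls add to the median of -0.68 left without SLE replicates 2 and 5 thus stays open. Depth is argued against as the whole cause for the 200 to 211 intervals still tested after thinning every library to 8721 reads. There the median was -1.19 against -1.54 before. For the 766 intervals that no thinned draw tested depth stays open, since their median went from -2.95 to -0.76 without SLE replicates 2 and 5, and a pseudocount of 1 read of the shallowest library, which flattens low values in every library, brought the median of all intervals to -0.03. SLE replicates 2 and 5 may account for most of the pattern, with a median of -0.68 without them, and a difference between SLE and control NETs, which no further test addressed, also stays open.

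The miRNA lists ranked low and the rRNA list high in SLE with a preset correlation, 3 lists in all, but with an estimated correlation none did (adjusted p 0.639 for each), so copies that share reads, or other intervals that move together, may account for the calls. For the rRNA rank under the preset correlation, depth is argued against as the whole cause, since its adjusted p was 0.00242 without SLE replicates 2 and 5 and under 0.05 in 17 of 20 draws thinned to 8721 reads (0.000697 to 0.0646), although voom (0.388) and quantile normalization (0.515) ended the call. For miRNA depth stays open, since all miRNA were at 0.026 without SLE replicates 2 and 5 but at 0.721 with voom and 0.414 with quantile normalization, and the myeloid list was at 0.133 without these libraries. Of the 35 splits 7 gave as many lists (3 in the real split and 4 in the highest other), so chance is not excluded. For the control replicates that stand apart, the rRNA median relative to all intervals was 0.32 without them and 0.63 with them, a value between both bounds set for the test, so this explanation cannot be told apart from a difference in disease, which stays open.

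The 4 intervals lower in the LDG library were all at 0 reads there, with a Poisson p of 0.0354 for the 7SL fragment and 0.132 to 0.235 for the other 3, not adjusted for the 4. Counting error alone gives fewer zeros than were seen: 6 intervals with 3 or more expected reads were at 0 in the LDG library and 8 and 4 in SLE replicates 2 and 5, where Poisson counts give 0.8, 0.7 and 0.3, so it cannot be told apart from a wider spread for the 4. Of intervals with as many expected reads as the 4, 39% (23 of 59) were at 0 in the LDG library and 27.8% and 36.8% in SLE replicates 2 and 5, where Poisson counts give 6.9, 6.4 and 4.9 intervals, so spread that shallow libraries share may account for the calls, and with a pseudocount of 1 read of the shallowest library 37 intervals were higher and 0 lower. A difference between low-density and normal-density cells stays open, and 1 library gives it no replicate.

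For YELLOW against BLUE, the real split and the highest other both gave 0 intervals, so that 10 of the 10 splits of the 6 libraries gave as many by construction, and 10 splits are too few for a share under 0.05.

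Libraries far from the others of their group gave 32 outlying values in 152 groups tested, each above the others. Dixon's test gives about 1 in 20 groups by chance for independent normal values. The values here need not be normal and many items overlap, so no excess over chance can be read from the count. SLE replicate 1 had 6.97% of reads in Y RNA (others 0.499 to 1.92), 0.211% in other transcripts (others up to 0.0501) and 23.8% in unannotated intervals (others up to 7.16). It also had 197891 RPKM at HY4 on chromosome 7, 191103 at HY4 on chromosome 3 (156871336 to 156871394), 930424 at the SLC4A7 interval and 1065 at SLC35F3. SLE replicate 5 (8721 reads) had 0.265% of the summed RPKM and 0.227% of reads in mitochondrial RNA (others up to 0.0375 and 0.0383), 1033 RPKM at mitochondrial rRNA from position 2594, 82054 at small-subunit rRNA on chromosome 2 from 133011913, and 3954 at MIR26B. SLE replicate 2 (13127 reads) had 3809 RPKM at the chromosome 8 interval, 21161 at the LTR12C repeat, 1259 at MIRLET7I and 1172 at the 5' end of B2M. SLE replicate 3 had 423087 RPKM at the PDE3A rRNA copy, 105 at USP34, 2949 at MIR223, 547 at SRGN and 148630 at U2 on chromosome 6. SLE replicate 4 had 1223 RPKM at the chromosome 17 tRNA, 8298 at the chromosome 14 tRNA, 17.8 at MIR146B, 1264870 at small-subunit rRNA on chromosome 16 from 33963696 and 48.4 at VTRNA1-3. Control replicate 1 had 194128 RPKM at small-subunit rRNA on chromosome 2 from 133012688 and 10681 at the LTR12C repeat. Control replicate 2 had 429 RPKM at PTMS, control replicate 3 had 777767 at the PDE3A rRNA copy, and control replicate 6 had 3706 at small-subunit rRNA from 133011913 and 1652 at MIRLET7B.

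YELLOW minus BLUE had opposite signs in the SLE code and in both control codes for 3 of 12 class shares, which was not tested and which 3 codes give by chance for 1 class in 4. The differences in the SLE code were -0.0991 points for miRNA (0.0552 and 0.184 in control), 0.162 for protein-coding transcripts (-0.194 and -0.0983) and 11.1 for rRNA (-8.13 and -3.82).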

How the results depend on the processing

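The pseudocount of 1 read, voom, leaving out SLE replicates 2 and 5, leaving out control replicates 2, 3 and 4, and class shares in the YELLOW libraries were tests chosen only after the result was seen; the other alternatives here were planned, and the count models planned for deposited counts were not run. SLE against control gave 0 intervals in all other settings than the YELLOW libraries (29) and leaving out libraries in turn (0 to 31, the 31 without SLE replicate 4). The 29 and the 31 come from fits that keep shallow SLE libraries and cannot be told apart from a difference in depth. YELLOW against BLUE gave 16 without a filter and 3 for the colour term over 11 libraries, and 0 to 1 on leaving out libraries in turn (1 without control replicate 3 and 1 without control replicate 4). For the LDG library the 4 intervals became 13 with a pseudocount of 0.1, 13 without a filter, 0 with quantile normalization, 61 with median centring, 0 without trend and robust estimation, 37 with a pseudocount of 1 read, 0 with voom, 279 without SLE replicates 2 and 5, and 2 to 40 on leaving out libraries in turn (9, 24 and 40 without SLE replicates 1, 2 and 5, and 2 without each of control replicates 1, 3, 4, 5 and 6). The 3 lists became 6 with a pseudocount of 1 read, 1 in the BLUE libraries, 0 without control replicates 2, 3 and 4, and 0 with an estimated correlation. With quantile normalization they were again 3 but not the same ones: myeloid miRNA stayed (0.0442), rRNA (0.515) and all miRNA (0.414) did not, and mitochondrial RNA ranked high (0.00591) and tRNA low (0.0442). Without SLE replicates 2 and 5 they were rRNA, all miRNA and vault RNA (0.00914). No class share passed in any setting. The difference in intervals with a read ran from -786.2 to -551.3 on leaving out libraries in turn, with an exact permutation p of 0.0286 without SLE replicate 4, and was -251.5 without SLE replicates 2 and 5. The filter and the left-out libraries change how many intervals or libraries are tested. Median centring raises every value of the 3 libraries under 20000 reads, whose median over the tested intervals is 0. Calls and turns under it thus cannot be told apart from depth. For the remaining settings the cause was not tested. Leaving out SLE replicates 2 and 5 also sets the LDG library against SLE libraries of far greater depth only. Without a filter the calls for the LDG library went in both directions, most of them higher, where the main calls were all lower.

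List directions that turned did so with adjusted p far from the threshold, except where fry, which compares with no other interval, replaced the ranking: 0.067 for mitochondrial RNA, 0.169 for rRNA and 0.595 for mature neutrophil messenger RNA. The snoRNA list turned at adjusted p = 0.818 with a pseudocount of 10, 0.49 with quantile normalization, 0.969 with a pseudocount of 1 read, 0.567 with voom, 0.896 without a block, 0.8 without SLE replicates 2 and 5 and 0.977 with an estimated correlation. The snRNA list turned at 0.99 without a block, 0.821 in the BLUE libraries, 0.627 without SLE replicates 2 and 5 and 0.977 with an estimated correlation. The 7SK and 7SL list turned at 0.969 with a pseudocount of 1 read, 0.821 in the BLUE libraries and 0.765 without control replicates 2, 3 and 4, the let-7 family at 0.821 in the BLUE libraries, Y RNA at 0.821 there and 0.898 without control replicates 2, 3 and 4, and mitochondrial RNA at 0.8 without SLE replicates 2 and 5. Voom ranked rRNA at 0.388, miRNA at 0.721 and myeloid miRNA at 0.144. It ranked tRNA (0.00817) and Y RNA (0.046) below the other intervals, although their medians were above 0 (0.14 and 0.12, against 0.72 for all). These ranks, like those with quantile normalization, rest on the preset correlation. The estimated correlation was run on the main fit only, with a camera adjusted p of 0.977 for tRNA and mitochondrial RNA and 0.894 for Y RNA.

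The class shares that changed sign are given as SLE minus control in percentage points. Unannotated RNA, at 24.3% of the summed RPKM in SLE and 23.6% in control (means over codes), is a large class and the others are small. With 11 libraries taken as independent, other small RNA was at -0.025 and unannotated RNA at -1.09. In the BLUE libraries miRNA was at 0.0367, mitochondrial RNA at -0.00212 and protein-coding transcripts at 0.596. As shares of reads, other small RNA was at -0.0113, protein-coding transcripts at 0.0406 and unannotated RNA at -3.12, and without SLE replicates 2 and 5 as well, mitochondrial RNA was at -0.00353 and protein-coding transcripts at 0.297. Without SLE replicates 2 and 5 mitochondrial RNA was at -0.00666 and snRNA at 0.059, and without control replicates 2, 3 and 4 other transcripts were at -0.0394 and protein-coding transcripts at 0.998. In the YELLOW libraries other small RNA was at -0.188, other transcripts at -0.0245 and unannotated RNA at -10.5. Leaving out libraries in turn gave -0.111 to 0.0871 for other small RNA, -0.0782 to 0.0689 for other transcripts, -0.384 to 0.421 for protein-coding transcripts and -7.12 to 4.91 for unannotated RNA.

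Among the named intervals, log2 fold changes of SLE against control that turned were the following, none past the threshold. With median centring: 7SL RNA on chromosomes 13 (3.48) and 9 (3.25), HY4 on chromosomes 3 (2.48) and 7 (2.36), MIR146B 0.06, MIR24-1 2.49, MIR26B 1.16, MIRLET7I 1.97, PDE3A rRNA 2.25, U1 2.20, U2 2.60, SRGN 1.76, B2M 1.47, RPLP1 2.07, tRNA-Glu-GAG 1.69, tRNA-Gly-GGY 2.18, 1.58 and 1.86, and the SLC4A7 (2.00), GFM2 (3.57) and chromosome X (2.02) intervals. With quantile normalization: 7SL RNA on chromosomes 13 (0.25) and 9 (0.17), MIR146B 0.16, MIR24-1 1.59, MIRLET7I 0.63, SRGN 1.73, B2M 0.57 and RPLP1 2.22. With voom: 7SL RNA on chromosome 9 0.07, MIR146B 0.80, MIR24-1 1.25, MIRLET7B 0.72, mitochondrial rRNA from position 1700 0.10, SRGN 2.25, B2M 1.07, RPLP1 1.85 and GFM2 0.14. With a pseudocount of 1 read: MIR24-1 0.17, MIRLET7I 0.21, SRGN 0.03 and B2M 0.12. Without SLE replicates 2 and 5: 7SL RNA on chromosome 9 0.14, MIR24-1 0.98, MIRLET7B 0.22, SNORD104 -0.22, SNORD35A -0.17, SRGN 1.56, RPLP1 0.25 and GFM2 0.73. Without control replicates 2, 3 and 4: 7SL RNA on chromosome 13 0.66 and MIR24-1 0.18. In the BLUE libraries: 7SL RNA on chromosome 13 0.19, MIR24-1 2.72, MIRLET7I 1.62, SNORD104 -0.17 and mitochondrial rRNA from position 2594 -0.02. SNORD104 was at -0.56 in the YELLOW libraries, -0.03 without the colour term, -0.12 without a filter and -0.34 without a block, and GFM2 at 0.17 in the YELLOW libraries, 0.11 with codes averaged and 0.06 without the colour term. Leaving out libraries in turn gave -0.70 to 0.36 for 7SL RNA on chromosome 13, -2.03 to 1.30 for MIR24-1, -0.56 to 0.26 for SNORD104 and -0.91 to 0.85 for GFM2. Leaving out 1 SLE library moved the SLE mean RPKM by over 1.5-fold in 38 of the 49 named intervals, and leaving out 1 library of either group turned the direction of the means in 12. Depth limits most the 3 libraries under 20000 reads, where the floor of 3 reads is 0.0383% to 0.0567% of listed reads.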

Other observations

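The comparisons of tRNA and Y RNA make-up and the test of promoter positions were chosen only after the result was seen.

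Within tRNA reads, fragments of glutamate and glycine tRNAs led in both groups. Glycine tRNA took 39.2% ± 16.7 of tRNA reads in control and 33.0% ± 13.2 in SLE (SD, n = 4 codes each), and glutamate tRNA 34.6% ± 16.0 and 26.7% ± 11.7. Lysine tRNA took 8.45% ± 4.37 and 13.2% ± 7.48, and 25.8% of the 333 tRNA reads of the LDG library. Asparagine tRNA took 0.249% ± 0.0495 in control and 0.796% ± 0.402 in SLE, with an exact permutation p of 0.0286, the smallest possible, and an adjusted p of 0.371 over 13 tRNA kinds. Within Y RNA reads, HY4 took 66.0% ± 6.75 in control and 76.9% ± 5.98 in SLE and HY5 33.5% ± 7.02 and 22.5% ± 5.91, each with an exact permutation p of 0.0571 and an adjusted p of 0.0857 over 3 kinds. SLE replicates 2 and 5 held only 558 and 220 tRNA reads and 147 and 63 Y RNA reads. Without them, and so with fewer codes to permute, the exact permutation p was 0.0667 for asparagine tRNA and 0.133 for HY4 and for HY5.

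Intervals near promoters of protein-coding genes lay mostly downstream of the start site, and RNA of these libraries starting at promoters was a candidate explanation. Among intervals of protein-coding biotype within 100 nt of a start site, 222 of those with a read lay downstream and 11 upstream (95.3% downstream), against 324 and 21 (93.9%) of those at 0 in all 12 libraries. The Fisher exact p was 0.579, but intervals at 0 leave at most 6.1 points of room for a higher percent, so this comparison decides little. Unannotated intervals nearest to a protein-coding promoter leave more room. Within 100 nt, 199 of those with a read lay downstream and 34 upstream (85.4%), against 276 and 58 (82.6%) of those at 0. Neither pair shows a clear excess downstream in intervals with reads. The second pair was not tested, so the explanation stays open.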
